A study of Homo sapiens with 8 samples.

How the data were processed

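RNA was measured by sequencing in 8 human cancer cell lines with 1 library per line, per the labels. Cells had been cultured for 48 hours in plates before extraction, and the labels give a range of passages for each line. The authors deposited a table of FPKM values (fragments scaled by transcript length and by the total of mapped fragments) for each line, with 58202 Ensembl gene identifiers beside gene symbols, per the file headers. Per the submitters' processing notes the tools included CASAVA 1.4, TopHat2 2.0.8 and SAMtools 1.0, and the genome build was GRCh37. The program that estimated FPKM and its annotation release are not given in the sources used here, nor whether reads were assigned by strand.

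FPKM divides by transcript length, so short RNAs receive very large values from few fragments. Values above 100000 occurred for AC002066.2 in KLE and HEC59 and for AC055723.1 in 1321N1. Without these values, the FPKM of a line summed to between 376880 and 511451. FPKM holds no read totals, so the absolute depth of each library is unknown and no counting interval is given. Low values moved in steps of whole reads, and the commonest ratio of values under 0.1 between 2 lines therefore gives their relative depth. Of the 828 to 1481 genes with such values in both lines of a pair, 6.55% to 24.4% lay within 0.03 (log2) of that ratio, and the 28 pairs gave the same depths to within 0.00778 (log2). Relative to KLE, the shallowest line, depth was 1.17 in COV318, 1.26 in H716, 1.35 in H661 and in HEC59, 1.48 in H146, 2.00 in H522 and 2.67 in 1321N1. The steps also divided the lines into 2 sets, H522, H661, KLE and H716 against 1321N1, HEC59, COV318 and H146. Within sets 20.2% of genes lay at the commonest ratio and between sets 10.7%, a difference of 9.51 percentage points, and the next of the 35 splits of the lines into equal sets gave 2.87. From values under 0.03 to values of 0.1 to 0.5, the commonest ratio moved by a median of 0.04 (log2) within sets, with a range of 0.01 to 1.05, and by 0.27 between sets, with a range of 0.14 to 1.83. The largest moves within sets were those of H522 with KLE and of 1321N1 with HEC59 and COV318. Between sets the log2 ratio of KLE to 1321N1 moved from 1.42 to -0.41. Agreement among the pairs cannot show an offset shared by a whole set, so the relative depths are uncertain between sets. The labels give no batch. The sets come from the steps alone, and the levels of genes were not compared between them. The sets follow the order of the samples in the series, and what made their steps differ was not tested. Whether the sets coincide with the lines that do and do not respond to ibrutinib is unknown, so an overlap with response cannot be excluded. Lung and endometrial lines occur in both sets, and fits with the set as a term were added. Each line had 12205 to 13300 genes at an FPKM of 1 or more, and 23046 genes were listed at 0 in all lines. None of the 10 housekeeping genes was listed at 0. No pair of lines held identical values. Mitochondrial genes made up between 4.37% of the summed FPKM in 1321N1 and 16.1% in HEC59, after leaving out values above 100000.

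Gene types were taken from GENCODE v29, which is annotated on GRCh38. It was used for gene types and for choosing among identifiers that share a symbol, without coordinates, and 82.2% of the identifiers were found in it. Symbols are those of the files.

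The series design divides the lines into 4 that respond to ibrutinib and 4 that do not. The labels do not assign lines to these groups, so this comparison was not made and no line's response was inferred. Lines were grouped by the tissue in the labels: lung (H522, H661 and H146), endometrial (KLE and HEC59), cecum (H716), glial (1321N1) and ovarian (COV318). Lines of a tissue are different tumours, not repeat cultures, so p-values measure the spread between lines, and a tissue's difference includes those of its lines. Replicate numbers are in accession order and pair nothing.

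Values were analysed as log2(FPKM + 1), which understates the differences of genes at low levels. The 15650 genes with an FPKM of 1 or more in at least 2 lines were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Lung lines were compared with the other 5 lines, endometrial lines with the other 6, and lung with endometrial lines in a fit of all 5 tissues whose spread comes from the lung and endometrial lines. Of 22 gene lists, 21 had at least 3 genes past the filter and were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The list of immune cell markers was not tested. ERBB4 was correlated with 15 genes and list scores by Pearson's r and Spearman's rho with exact permutation tests over all 40320 pairings, two-sided, and Benjamini-Hochberg adjustment over the family. NRG3, EREG, BTK and ESR1 were left out of that family because they were below an FPKM of 1 in 7 or more lines. Similarity was the mean Spearman correlation of line pairs from the same tissue minus that of pairs from different tissues, with an exact permutation of the tissue labels, one-sided. List scores are means of log2(FPKM + 1) over all members. Counts of list genes as higher or lower compare group means on this scale, so single lines can overlap. Python 3.11 scripts used numpy, pandas, scipy and matplotlib.

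The tests, gene lists, partners, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each tissue comparison, the 10 higher and 10 lower genes with the largest difference among those past the threshold without overlap between groups. Where fewer than 5 genes passed, it took instead the 10 in each direction with the smallest unadjusted p, no overlap and a log2 difference of at least 1, described as not passing unless they did. For each line it took the 5 genes with the largest margin over the highest of the other 7 lines. XIST and Y-linked genes were left out of naming.

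The fit was tested on simulated data with 200 changed genes among 15650, in 5 runs. For lung lines against the others it recovered 64.2% of genes changed by 3 on the log2 scale and 92.6% of those changed by 6. For endometrial lines against the others it recovered 54.0% and 92.0%, and for lung against endometrial lines 12.8% and 74.6%. Unchanged genes called per run averaged 7.2, 5.6 and 4.6 in the same order. These shares hold for 200 changed genes with independent values. They do not give the power in the data, where 4, 1 and 1 genes passed and the adjustment was therefore stricter. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at an FPKM of 5, quantile and upper-quartile normalization, eBayes without trend and robust eBayes, other list tests, other correlation measures and gene sets, other detection levels, and leaving out each line. Restricting tests to protein-coding genes, the set of lines as a term, similarity and correlations of ERBB4 within sets and, for the closing section, a list of interferon-response genes and MAPK feedback targets as a partner of ERBB4 were added after the data were seen.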

Results

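Gene expression was profiled by RNA sequencing in 8 cancer cell lines that express ERBB4, a receptor tyrosine kinase for neuregulins. The series was designed around the response of these lines to ibrutinib, an inhibitor of Bruton's tyrosine kinase (BTK). The lung lines were H522 from a non-small cell lung cancer, H661 from a large cell cancer and H146 from a small cell cancer. KLE and HEC59 were endometrial, H716 came from the cecum, 1321N1 was glial and COV318 ovarian. Each line had 1 library, and 12205 to 13300 genes reached an FPKM of 1 per line. The files give FPKM and not counts. The absolute depth of the libraries is unknown, and their relative depth ranged from 1 in KLE to 2.67 in 1321N1. Because the labels do not say which 4 lines responded, the lines are described singly and by tissue of origin.

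ERBB4 (ENSG00000178568) was detected in all 8 lines, from an FPKM of 13.4 in H146 to 102 in H522. HEC59 and H716 were also high, at 85.3 and 76.1, and COV318, KLE, H661 and 1321N1 lay between 28.5 and 36.3. The other ERBB receptors varied more from line to line. EGFR reached 32.4 in KLE but only 0.392 in H522 and 0.00692 in H146, ERBB2 ranged from 0.868 in H146 to 22.0 in H522, and ERBB3 was highest in HEC59 at 10.7. H146 therefore had the lowest values of EGFR, ERBB2 and ERBB4, and its ERBB3 stood at 2.34.

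Of 11 ERBB ligands, 10 were detected at an FPKM of 1 or more in at least 1 line. NRG1, which encodes a ligand of ERBB3 and ERBB4, was the most abundant, at 81.9 in H522, 45.4 in H661, 21.3 in H146, 19.2 in KLE and 13.5 in 1321N1, and stayed below 1 in H716, HEC59 and COV318. NRG4 reached 1 in 7 lines at lower levels, with 11.9 in COV318 and at most 2.28 elsewhere. HBEGF reached 36.4 in H661, EREG 28.7 in H522, EGF 10.9 in H661, and AREG 10.9 in HEC59 and 9.38 in H522. H716 had no ligand at an FPKM of 1. With detection set at an FPKM of 5, 6 ligands remained detected in some line.

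**Figure D1:**
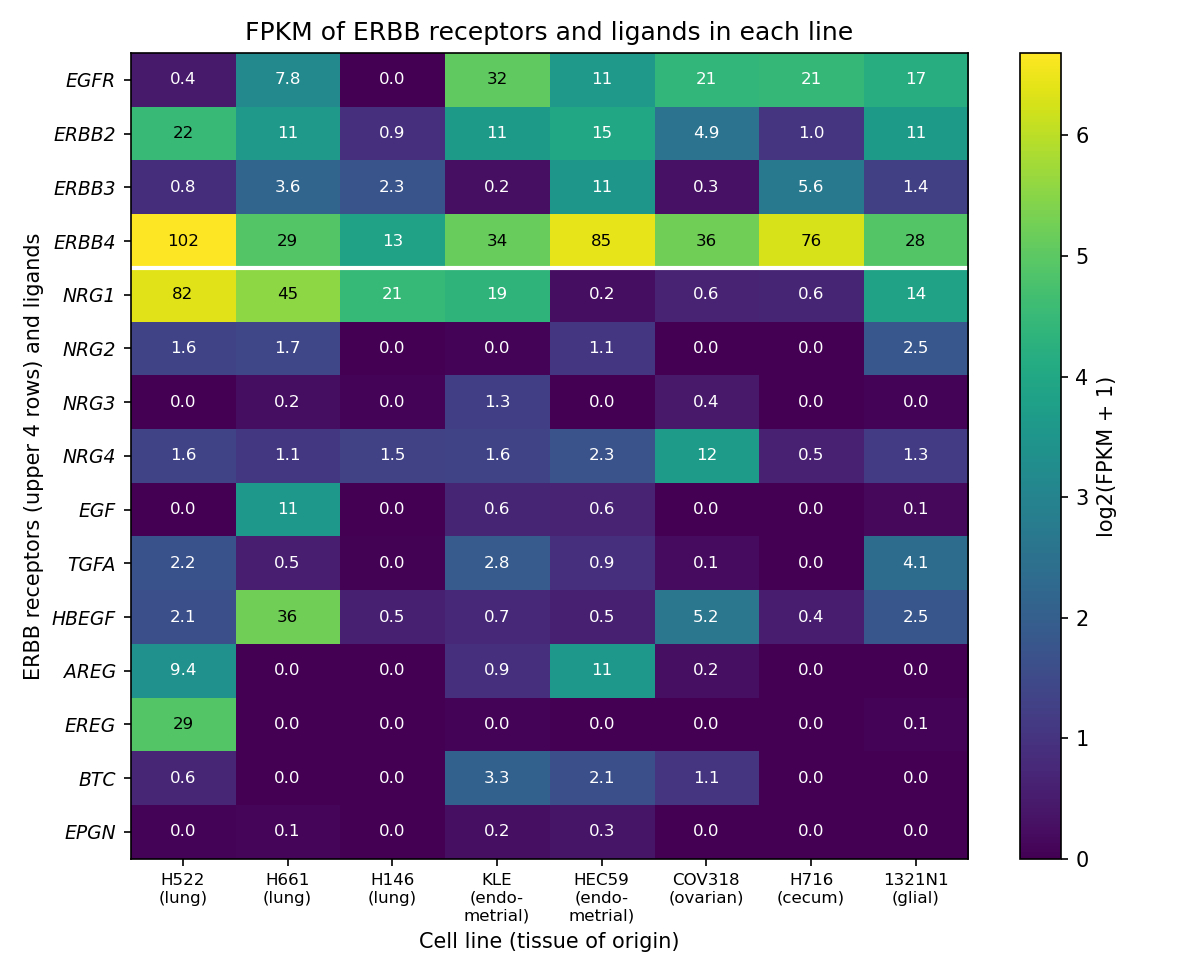
FPKM of the 4 ERBB receptors and 11 ERBB ligands (rows) in the 8 lines (columns), with colour showing log2(FPKM + 1) and the FPKM printed in each cell; values under 0.05 print as 0.0. ERBB4 lies between 13.4 and 102 in all lines, whereas NRG1 spans 0.185 in HEC59 to 81.9 in H522.

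BTK itself did not exceed an FPKM of 0.112 in any line. Among 12 kinases of the ibrutinib list, 6 were detected in at least 1 line, and CSK and YES1, both kinases of SRC signalling, were detected in all 8. YES1 ranged from 9.59 in H716 to 143 in H661. TEC, a kinase of the BTK family, reached 4.47 in HEC59, and TXK, of the same family, 5.39 in COV318. JAK3 was detected in H661 at 1.44. Only 3 of the 12 reached an FPKM of 5 in any line. The list holds no ERBB receptor, so these counts do not cover the receptors described above. Of the 12 genes of the B-cell receptor pathway list, 6 were detected in at least 1 line. CD79A, CD79B and MS4A1 stayed below 1 in all lines, while LYN and PLCG2 were each detected in 6. SYK was at 15.5 in H146 and 11.5 in KLE, and PAX5 at 5.79 in H146 and 5.76 in H716, both below 1 elsewhere.

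No relation between ERBB4 and its 15 partners across the 8 lines passed the test. The largest r was with YAP1, a transcriptional coactivator of the Hippo pathway (r = 0.556, exact permutation p = 0.162, adjusted p = 0.812; rho = 0.714, p = 0.0576, adjusted p = 0.848). Without H522 and H146, the lines farthest from the median ERBB4 level, this r was -0.468. For the neuroendocrine score r was -0.433 (exact permutation p = 0.259; rho = -0.548, p = 0.171), and 0.395 without those lines. ERBB2 had r = 0.414 (exact permutation p = 0.306; rho = 0.595, p = 0.132), NRG1 r = -0.280 (p = 0.484; rho = -0.190, p = 0.665) and WNT5A, a ligand of non-canonical WNT signalling, r = -0.317 (p = 0.421; rho = -0.214, p = 0.619). Without H522 and H146 these were -0.371 for ERBB2, -0.796 for NRG1 and -0.0522 for WNT5A, and the 15 partners then spanned -0.835 for the mesenchymal score to 0.736 for ERBB3. When single lines were left out, r ranged from 0.0128 to 0.816 for ERBB2, -0.769 to -0.0813 for NRG1 and -0.576 to -0.0969 for WNT5A. The smallest adjusted p in the family was 0.812 for Pearson's r and 0.848 for Spearman's rho. With values centred and permuted within the 2 sets of lines with like read steps, of 4 lines each, no partner passed either (exact permutation over 576 arrangements, smallest adjusted p = 0.947), and r was 0.521 for YAP1, -0.434 for the neuroendocrine score, 0.385 for ERBB2, -0.514 for NRG1 and -0.0147 for WNT5A. WNT5A was detected in COV318, HEC59, 1321N1, H146 and KLE at 2.55 to 7.80, and its receptor ROR1 in KLE, H716, COV318 and 1321N1 at 5.27 to 16.5.

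The similarity of lines from the same tissue did not exceed that of lines from different tissues. The mean Spearman correlation across genes was 0.742 for the 4 same-tissue pairs and 0.741 for the 24 other pairs (difference 0.00102, exact permutation p = 0.473, one-sided; the smallest p possible was 0.000298). H522 and H661 correlated at 0.838, but their correlations with H146, the small cell line, were 0.688 and 0.678. H146 lay closest to H716 at 0.725. The closest pair of all was KLE and COV318, an endometrial and an ovarian line, at 0.846. HEC59 was nearer to COV318 (0.788) than to KLE (0.764). Genes are not independent replicates, so these correlations describe the profiles. Without H146 the difference was 0.0430 (exact permutation p = 0.0667), and it was -0.0165 without H522, -0.0103 without H661, -0.00508 without KLE and -0.0102 without HEC59. Of the same-tissue pairs, H522 with H661 alone lies within a set of lines with like read steps, at 0.838 against 0.724 to 0.763 for the other 5 pairs of that set, and the other set holds no same-tissue pair. With pairs within and between sets each centred on their mean, the difference was 0.00103 (exact permutation of tissues within sets, one-sided, p = 0.556).

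**Figure D2:**
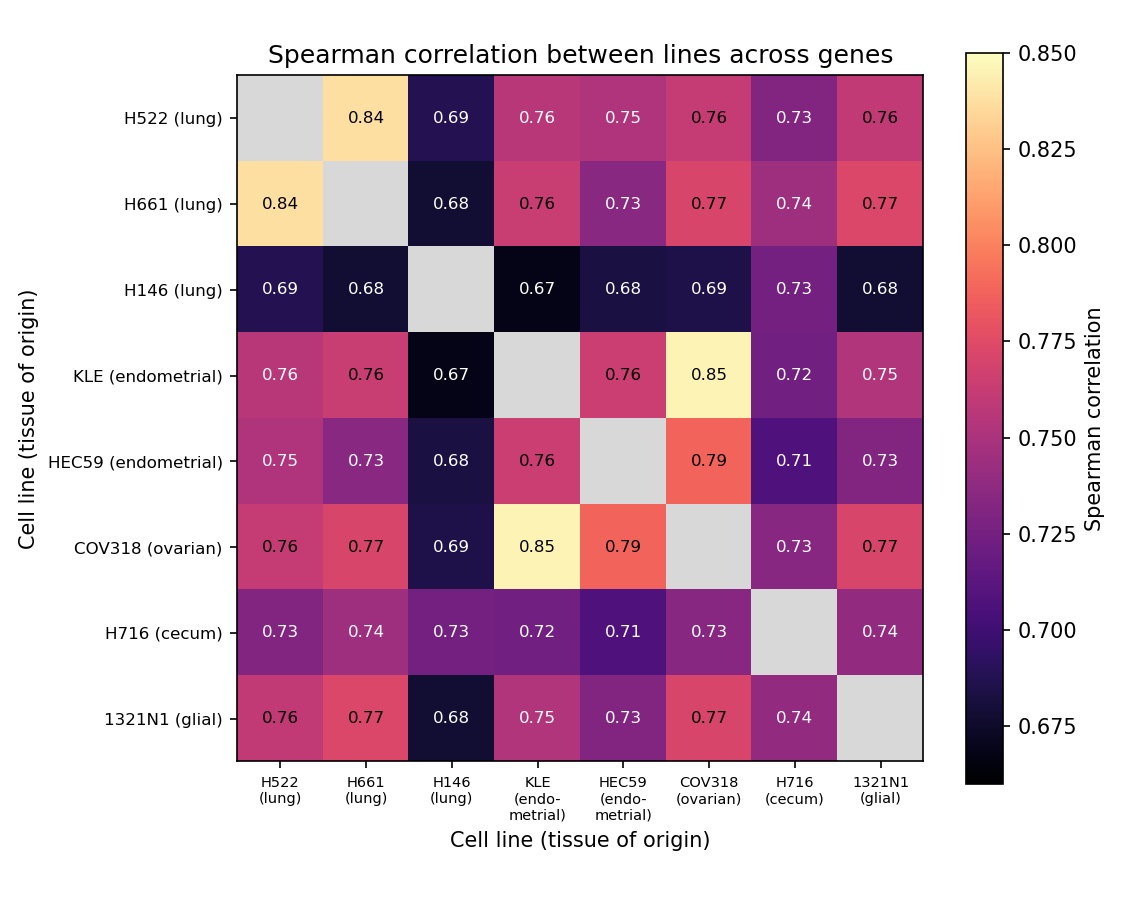
Spearman correlation across the 15650 tested genes between each pair of lines, lines on both axes with their tissue, colour and printed number giving the correlation. H146 has the darkest row, with values from 0.669 to 0.725, and KLE with COV318 is the brightest cell at 0.846.

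Lineage lists set several lines apart. The neuroendocrine score, a mean of log2(FPKM + 1) over 18 genes, was 5.22 in H146 and 4.13 in H716, and at most 1.45 in the other lines. CHGA and CHGB, which encode granins of secretory granules, were at 15.4 and 55.6 in H716 and at 7.59 and 12.8 in H146. The mesenchymal score was highest in 1321N1 at 6.19 and lowest in H146 at 1.02, where VIM was at 0.219. Epithelial scores were highest in HEC59 (3.81), KLE (3.47) and H146 (3.31) and lowest in 1321N1 (0.59).

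Tissue markers were uneven. The Mullerian list scored 3.01 in HEC59, 2.99 in KLE and 2.29 in COV318 and at most 1.17 elsewhere. The intestinal list scored 2.07 in H716, where CDH17, an intestinal cadherin, reached 137. Surfactant genes SFTPA1 and SFTPA2 were listed at 0 in all lines, SFTPB and SFTPC stayed below 1, and NKX2-1, a lung lineage transcription factor, was detected in H661 alone at 11.2. The glial list was low in the glial line 1321N1 (0.31), where GFAP was at 3.10 and OLIG1 at 0. Fibroblast markers scored 4.37 in 1321N1, led by COL6A3 at 315. Immune and endothelial scores stayed below 1 in all 8 lines.

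**Figure D3:**
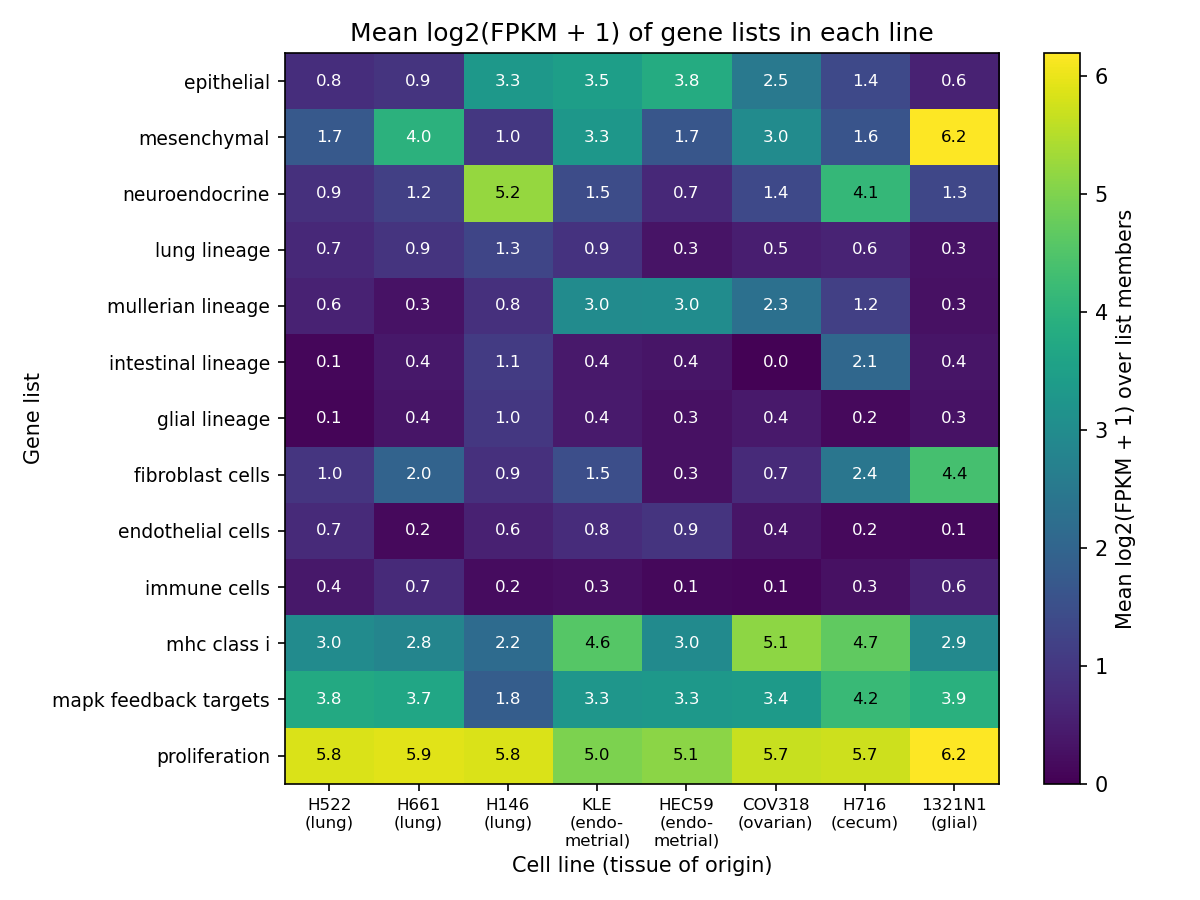
Mean log2(FPKM + 1) over the members of 13 gene lists (rows) in the 8 lines (columns), given by colour and number. The neuroendocrine row is high in H146 (5.22) and H716 (4.13), and the mesenchymal row is highest in 1321N1 (6.19).

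The lung lines differed from the other lines in 4 genes. CDH7 (ENSG00000081138), a cadherin cell adhesion gene, was at 42.0, 45.6 and 37.6 in H522, H661 and H146 and at most at 0.209 in the other 5 lines, a log2 difference of 5.28 (SE 0.33, limma adjusted p = 0.000572). On the log2 scale its mean was 5.41 ± 0.14 (SD, n = 3) in the lung lines and 0.14 ± 0.10 (SD, n = 5) in the others. GRIA2 (ENSG00000120251), which encodes an AMPA glutamate receptor subunit, was at 180, 29.9 and 52.3 in the lung lines and at most 1.23 in the others (log2 difference 5.49, SE 0.58, adjusted p = 0.0210). CXXC5 (ENSG00000171604), a zinc finger gene, was lower in all 3 lung lines, at 2.76 to 9.89 against 72.4 to 104 (log2 difference -3.71, SE 0.38, adjusted p = 0.0206). SNX18P7 (ENSG00000234373), a processed pseudogene of SNX18, was at 5.32 to 19.1 in the lung lines and listed at 0 in all others (adjusted p = 0.0483). Its values are uncertain, since how reads shared by similar copies were assigned is not given in the sources used here.

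Further genes without overlap between the groups did not pass the threshold. Higher in the lung lines were BARX1, ANKRD18B, INA, MED12L, TEX15, TMEM35 and the small nucleolar RNA U3, with adjusted p between 0.0587 and 0.105. INA, a neuronal intermediate filament gene, was at 13.7 to 85.0 in the lung lines and at most 3.60 elsewhere. On the lower side were PRRG1, ASS1, TRIP6, TMEM173, MGST1, SP100, TNFAIP2, TRIM38 and LIMCH1 (adjusted p 0.0587 to 0.105). ASS1, an enzyme of arginine synthesis, was at 4.43 to 4.66 in the lung lines and 60.8 to 321 in the others. TMEM173, which encodes the STING adaptor of cytosolic DNA sensing, was at most 0.628 against at least 6.49. ERBB4 itself did not differ (log2 difference -0.44, SE 0.639, adjusted p = 0.958). At an unadjusted p under 0.05 there were 930 genes, and 673 genes (chance gives 3.57% of genes) had no overlap between the groups. CDH7 was called under all 18 alternatives (adjusted p 0.000207 to 0.00915), GRIA2 under 11 and CXXC5 under 13. With no filter the adjusted p was 0.131 for GRIA2 and 0.0807 for CXXC5, with a pseudocount of 5 it was 0.108 for GRIA2, and without KLE, 1321N1, HEC59 or COV318 the adjusted p was 0.0576, 0.0664, 0.0597 and 0.0773 for GRIA2 and 0.0535, 0.0664, 0.0534 and 0.0773 for CXXC5. The number of genes called was 16 without H146, 13 without H716, 8 without H661, 2 without 1321N1 or HEC59, 1 without COV318, and 2 (CDH7 and CXXC5) with the set of lines as a term, where GRIA2 had an adjusted p of 0.0852 and SNX18P7 0.0934; SNX18P7 was called under 5 of 17 alternatives.

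**Figure D4:**
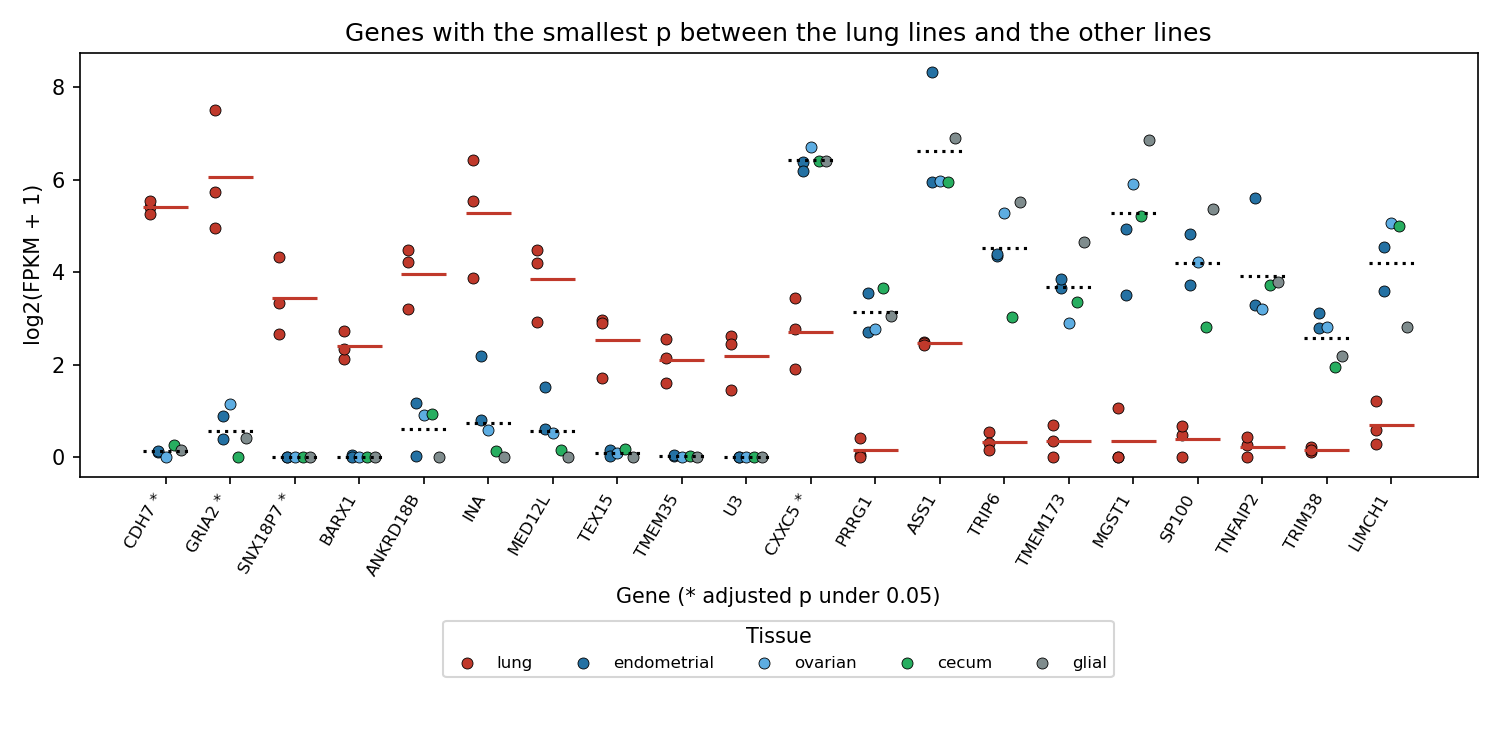
log2(FPKM + 1) of the 20 genes named for the lung comparison; points are lines coloured by tissue, solid bars are means of the 3 lung lines and dotted bars means of the other 5. Stars mark CDH7, GRIA2, SNX18P7 and CXXC5, whose adjusted p was under 0.05.

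Among the lists, Mullerian and MHC class I genes were lower in the lung lines than other genes. Of 11 Mullerian genes tested, 10 had a mean below that of the other lines (median log2 difference -1.32, camera adjusted p = 0.000288), and all 10 MHC class I genes did (median -1.17, adjusted p = 0.000288). With an estimated correlation the adjusted p was 0.577 for both. The lung lines were not alone at the low end: the MHC class I score was 2.99 in H522, 2.82 in H661 and 2.17 in H146, and 2.92 in 1321N1 and 2.96 in HEC59, against 4.56 in KLE, 4.68 in H716 and 5.14 in COV318. The Mullerian score of 1321N1 (0.29) lay below those of the lung lines (0.31 to 0.85). For these lists, no member passed, over all genes or adjusted over the list alone. HLA-B, which encodes an antigen-presenting chain, differed by -2.40 (SE 0.984), and NLRC5, a transactivator of MHC class I genes, by -1.45 (SE 0.440). Adjusted over the list alone, EGFR was lower among 4 ERBB receptors (log2 difference -3.12, SE 0.690) and SOX2, a stem cell transcription factor, higher among 5 lung lineage genes (3.78, SE 0.923). Neither passed over all genes (limma adjusted p = 0.306 and 0.435). SOX2 overlapped between the groups, at 72.0, 7.48 and 55.7 in H522, H661 and H146 and at 9.34 in KLE. Over the 7 ERBB ligands tested, NRG1 differed by 3.51 (SE 1.03, adjusted p = 0.603), and the list did not pass (camera adjusted p = 0.525). The proliferation list had a camera adjusted p of 0.142, and 0.0485 after quantile normalization (adjusted p = 0.659 with an estimated correlation). Without single lines other lists passed at the preset correlation, but with an estimated correlation their adjusted p was 0.561 to 0.902. At the preset correlation, neuroendocrine genes were higher without H522 (adjusted p = 0.000963), H661 (0.00886) or H716 (0.0240), lung lineage genes higher without H522 (0.0164) or H661 (0.0446), mesenchymal genes lower without H661 (0.00886), and epithelial genes lower without 1321N1 (0.00950) or H146 (0.00189), with proliferation genes higher without 1321N1 (0.0111).

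Mean levels of most Mullerian and epithelial genes were higher in the endometrial lines than in the other lines. PAX8, a transcription factor of the Mullerian tract, was at 45.7 in KLE and 185 in HEC59 (log2 difference from the other lines 4.56, SE 1.44), SOX17, a transcription factor of the same tract, at 10.3 and 56.1 (3.85, SE 1.29), and MUC16, which encodes the CA125 antigen, at 8.18 and 2.97 (2.56, SE 0.383). All 11 Mullerian genes tested had a higher mean (median 2.56, camera adjusted p = 6.74e-11). The adjusted p was 0.0573 for camera with an estimated correlation and 0.0525 for fry. Adjusted over the list alone, 6 passed: PAX8, EMX2, MUC16, MSX1, SOX17 and FOLR1. Of 14 epithelial genes 13 were higher (median 2.38, camera adjusted p = 2.55e-09; adjusted p = 0.179 with an estimated correlation and 0.358 with fry), and CDH1, KRT8, KRT18, KRT19 and CLDN4 passed when adjusted over the list alone. None of these genes passed over all genes. COV318, which counts among the other lines here, was itself at 72.6 for PAX8 and 26.7 for SOX17. HOXA9 and HOXA10 were higher in H716 (25.8 and 48.5) than in KLE (5.50 and 5.30) or HEC59 (18.1 and 18.9). WT1 was at 0.408 in HEC59 and 12.4 in H522. High epithelial scores were not limited to the endometrial lines either. H146 scored 3.31 and COV318 2.52, against 3.47 in KLE, 3.81 in HEC59 and at most 1.36 elsewhere.

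Proliferation genes were lower in the endometrial lines, in 13 of 14 cases (median log2 difference -0.94, camera adjusted p = 1.20e-05; adjusted p = 0.0573 with an estimated correlation, and 0.0347 with fry). AURKA and PLK1, mitotic kinases, RRM2, a subunit of ribonucleotide reductase, and BIRC5, an inhibitor of apoptosis, passed when adjusted over the list alone. RRM2 was at 58.0 in KLE and 76.8 in HEC59 and at 170 to 604 in the others (log2 difference -2.06, SE 0.474). MKI67 did not follow (0.26, SE 0.468). The median over all genes was -0.11 in this comparison, and -0.00408 after upper-quartile scaling, so differences near this size carry no direction. Neuroendocrine genes were lower in 14 of 16 cases (camera adjusted p = 0.0360; adjusted p = 0.797 with an estimated correlation, 0.154 with a pseudocount of 0.1 and 0.0589 with the set of lines as a term), and without H716, HEC59 or H146 the adjusted p was 0.298, 0.561 and 0.332. Without KLE the ERBB receptors passed as higher (camera adjusted p = 0.0480; adjusted p = 0.260 with an estimated correlation). BTC, which encodes an ERBB ligand, passed when adjusted over the ligand list alone (1.57, SE 0.421).

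By single genes, the endometrial lines differed from the others in AC002066.2 only (ENSG00000216076, adjusted p = 1.13e-07). This identifier, which is absent from GENCODE v29, was at 1970000 in KLE and 449044 in HEC59 and listed at 0 elsewhere. The summed FPKM of KLE was 2452060 with this value and 482065 without it. Short RNAs can reach such values from few fragments, and the length and fragments of AC002066.2 are unknown here. The call therefore does not establish a high shared expression. Genes without overlap that did not pass included KCNK1, MPZL2, KLK6, IQGAP2, PTAFR, MUC16, CALB1, KLK8 and TSPAN1 on the higher side (adjusted p 0.0942 to 0.130). CALB1, which encodes the calcium-binding protein calbindin, was at 1752 in HEC59 and 122 in KLE and at most 13.5 elsewhere. On the lower side were C3orf14, UQCRH, ZNF655, NCAPG, KATNAL1, PBX3, SNX17, MANF, RRM2 and MARCKS (adjusted p 0.104 to 0.570). UQCRH, which encodes a subunit of mitochondrial complex III, was at 24.6 in KLE and 2.97 in HEC59 and at 147 to 400.5 elsewhere. Of the 15650 genes tested, 755 had an unadjusted p under 0.05 and 1090 had no overlap (chance gives 7.14%). Both numbers lie slightly below what chance gives. Without COV318, 30 genes were called, among them SOX17, EMX2, CALB1 and IQGAP2. The number was 5 without H146, 4 without KLE and 2 without HEC59, and when protein-coding genes were tested alone limma called 0, with 648 at an unadjusted p under 0.05.

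In the direct contrast of lung with endometrial lines, all 11 Mullerian genes had a lower mean in the lung lines (median log2 difference -2.76, camera adjusted p = 2.42e-12). The adjusted p was 0.0924 for camera with an estimated correlation and 0.0118 for fry. Single lines overlapped in some of these genes. WT1 was at 12.4 in H522 and 0.408 in HEC59, and WFDC2 at 81.8 in H146 and 12.8 in HEC59. Adjusted over the list alone, 7 passed, PAX8 by -5.83 (SE 0.775) and HOXA9, a homeobox gene, by -3.22 (SE 0.618) among them. Epithelial genes were lower in 13 of 14 cases (camera adjusted p = 1.63e-07; adjusted p = 0.613 with an estimated correlation and 0.827 with fry), with KRT19, KRT7, CLDN4 and ELF3 passing when adjusted over the list alone. Proliferation genes were higher in 12 of 14 cases (camera adjusted p = 0.000514; adjusted p = 0.256 with an estimated correlation and 0.0118 with fry). MHC class I genes had a lower mean in all 10 cases, although the score of HEC59 (2.96) lay below that of H522 (2.99) (camera adjusted p = 0.00431; adjusted p = 0.613 with an estimated correlation) and neuroendocrine genes higher in all 16 (camera adjusted p = 0.0179; adjusted p = 0.962 with an estimated correlation). For the neuroendocrine list the adjusted p was 0.650 without H146, in the opposite direction, 0.468 without HEC59, 0.103 without H716 and 0.0531 with a pseudocount of 0.1, and for MHC class I it was 0.545 without KLE and 0.118 without H146. THY1, a cell surface glycoprotein gene, passed when adjusted over the fibroblast list alone (3.20, SE 0.640).

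AC002066.2 alone passed over all genes in this contrast, lower in the lung lines (limma adjusted p = 0.00151), with the limit on its values given above. Genes with no overlap that did not pass were led on the higher side by CDH7 and JAM3, both cell adhesion genes (adjusted p = 0.129 and 0.171), followed by DLX2, B4GALNT1, TMEM246, ALDH1A1, GRIA2, TUBB2B, SLC29A1 and GPX7. ALDH1A1, a retinaldehyde dehydrogenase, was at 2318 in H522, 696 in H661 and 141 in H146, and at 3.19 in KLE and 0.287 in HEC59. On the lower side were GLIS3, IFI16, ARHGAP29, SPON1, IQGAP2, TRIP6, IFITM1, CFI and C1orf186. GLIS3, a Kruppel-like zinc finger gene, was at most 1.28 in the lung lines and at 91.4 and 133 in the endometrial lines, and IFI16, an interferon-inducible DNA sensor, at most 0.252 against 38.0 and 31.3. There were 867 genes at an unadjusted p under 0.05 and 3264 without overlap (chance gives 20%). limma called 0 genes without H522, without KLE, without HEC59, with no filter and among protein-coding genes alone, with 706, 891, 933, 1755 and 726 at an unadjusted p under 0.05.

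The remaining lists did not pass in any of the 3 comparisons. For the ERBB receptors the camera adjusted p was 0.226, 0.215 and 0.197, in the order lung against others, endometrial against others and lung against endometrial. Ibrutinib kinases gave 0.525, 0.715 and 0.960, the B-cell receptor pathway 0.416, 0.715 and 0.960, non-canonical WNT genes 0.525, 0.215 and 0.268, and WNT beta-catenin targets 0.546, 0.563 and 0.907. MAPK feedback targets gave 0.242, 0.752 and 0.907, drug handling genes 0.142, 0.715 and 0.780, and mesenchymal genes 0.233, 0.593 and 0.907. Hypoxia and glycolysis genes gave 0.525, 0.752 and 0.960, and housekeeping genes 0.525, 0.493 and 0.907. Lung lineage genes gave 0.142, 0.906 and 0.447, intestinal genes 0.922, 0.752 and 0.960, glial genes 0.922, 0.715 and 0.907, endothelial markers 0.939, 0.435 and 0.903, and fibroblast markers 0.525, 0.357 and 0.447. Of lists that passed elsewhere or were given above, ERBB ligands gave 0.388 for the endometrial lines and 0.907 for the direct contrast, and MHC class I genes 0.388 for the endometrial lines. Lung against others gave 0.226 for epithelial and 0.172 for neuroendocrine genes. Signs of median, mean and camera direction differed for non-canonical WNT, beta-catenin target, glial and endothelial genes in the lung comparison. They also differed for ERBB ligands and ibrutinib kinases in both others and for mesenchymal, glial and hypoxia genes in the direct contrast.

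The number of genes at least 3 on the log2 scale above the highest of the other 7 lines was 115 in H146, 113 in H716, 92 in 1321N1, 72 in KLE, 57 in H661, 51 in HEC59, 31 in H522 and 29 in COV318. With a pseudocount of 0.1 the order differed, with 434 in H146, 278 in 1321N1 and 262 in H716. No test applies to a line with 1 library. The 5 genes with the largest margin were mostly short non-coding RNAs and pseudogenes, which reach a large FPKM from few fragments and whose values are uncertain where similar copies share reads. In H522 they were RP11-296I10.5, AC060226.1, TRNAI2, U4 and U2, in H661 RP11-329L6.1, U11, RNA5SP228, SCARNA20 and U4. In HEC59 they were RNU6-69, RNA5SP429, RNA5SP259, AL133153.1 and U4atac, in COV318 MIR548O, MIR499A, RPL39P40, RNA5SP268 and SCARNA11, and in H146 RNA5SP300, AC023593.1, AC009065.3, Z95704.1 and AC079233.1. In 1321N1 they were AC055723.1, Z97632.1, AC006548.19, MIR222 and RNU6-33. KLE had RNU6-36, AC083862.1, U6atac, HIST1H2APS3 and KRT6A, a keratin gene at 215 with 0.487 in the next line. H716 had AC138783.13, GAS2 at 1669, CTD-2373N4.1, NNAT, an imprinted neuronal gene, at 1067, and SYNGR4 at 637, the protein-coding genes among these being at most 2.24 in the next line.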

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

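The comparison with other splits of the lines was chosen after the values were seen. Of 66 levels and list scores compared across the 8 lines, 7 had a line far from the rest, with a gap to the nearest line, as a part of the whole range, above Dixon's critical value at 95% confidence. For independent items from a normal distribution, chance would give about 1 in 20, or 3 of these. Some list scores share genes with other items, and the lines come from 5 tissues. The 7 are therefore not shown to exceed chance. HBEGF was highest in H661, at 5.23 against 2.64 in the nearest line on the log2 scale (gap 0.551 of the range). NRG4 was highest in COV318, at 3.69 against 1.72 (0.644). VANGL1, a planar cell polarity gene, was highest in 1321N1, at 4.26 against 3.12 (0.582). H146 had the lowest ERBB receptor score, 1.63 against 3.14 (0.546), and the lowest score of MAPK feedback targets, 1.83 against 3.25 (0.602). It also had the highest glial score, 0.99 against 0.45 (0.595). Of the 12 genes in the glial list, 4 reached an FPKM of 1 in H146. They were led by PTPRZ1 at 36.1, against at most 0.404 in the other lines. The drug handling score was highest in H716, 1.92 against 0.98 (0.567), where ABCB1, an efflux transporter gene, was at 40.4.

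The 4 genes called between lung and other lines were set against other divisions of the same lines. Of the 56 splits into 3 and 5 lines, 9 called at least as many genes, the lung split included, so chance cannot be excluded as the source of this number. The split of KLE, HEC59 and COV318 from the rest called 31, the highest of the other splits. A number several times that of the lung split points to a structure of the samples, but it was picked as the highest, no chance value was computed for it, and splits of lines from mixed tissues called 14 (H522, H661 and 1321N1) and 10 (H716, HEC59 and H146).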

How the results depend on the processing

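Tests with protein-coding genes alone, with the set of lines as a term or within sets, and with MAPK feedback targets as a partner were chosen after the data were seen; where a result moved, the cause was not tested. Lung lines against the others, 4 genes, gave 11 with a pseudocount of 0.1, 2 with a pseudocount of 5, 1 with no filter and 2 with the set of lines as a term, and 1 to 16 when single lines were left out. Endometrial lines against the others, 1 gene, gave 4 with a pseudocount of 5, 20 with no filter, 0 for protein-coding genes (limma, 648 at an unadjusted p under 0.05), and 1 to 30 when single lines were left out. Lung against endometrial lines gave 0 with no filter, 0 for protein-coding genes (1755 and 726 at an unadjusted p under 0.05), and 0 to 1 when lines were left out.

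Of the gene lists, 2, 4 and 5 passed in the order lung against others, endometrial against others and lung against endometrial, against 0, 0 and 0 with an estimated correlation and 0, 1 and 2 with fry. Without single lines the number was 2 to 5 for the lung comparison and 3 to 5 for the direct contrast. The adjusted p of the neuroendocrine list ranged from 0.000963 to 0.489 in the lung comparison and from 5.20e-05 to 0.650 in the direct contrast. The 46 list results that passed under no setting took the opposite direction in 47 of 574 alternative values. No named gene changed direction: 997 values kept their side of the threshold, 28 passed it and 26 no longer did. The similarity difference ranged from -0.0165 to 0.0430 without single lines. None of the 15 partners of ERBB4 had an adjusted p under 0.05 in any alternative, nor when MAPK feedback targets were added over all 8 lines. Within sets r turned for NRG4 (0.147). After quantile normalization r turned for NRG4 (0.0128), ROR1 (-0.0353) and the epithelial score (0.0106). Without single lines r ranged from -0.550 to 0.631 for EGFR, -0.0575 to 0.418 for NRG2, -0.171 to 0.0993 for NRG4, -0.314 to 0.299 for ROR1, -0.0972 to 0.594 for ROR2, -0.0624 to 0.753 for YAP1, -0.505 to 0.106 for the epithelial and -0.761 to 0.150 for the neuroendocrine score. At an FPKM of 5, 6 ligands and 3 kinases of the ibrutinib list were detected. Genes that set H522, H661, KLE, H716, 1321N1, HEC59, COV318 and H146 apart numbered 116, 194, 192, 262, 278, 169, 105 and 434 with a pseudocount of 0.1. Protein-coding genes among them as deposited were 9, 35 and 40 in H522, H661 and KLE, 53, 25 and 15 in 1321N1, HEC59 and COV318, and 88 and 83 in H716 and H146. Without KLE or HEC59, AC002066.2 did not reach the filter, and the remaining endometrial line was assumed to vary like the other lines. Absolute depth is unknown, so counting error at low FPKM is not separated from differences between lines.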

Other observations

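The tests of interferon-response genes and of MAPK feedback targets, and the genes of the split named below, were chosen after the values were seen. KLE, HEC59 and COV318, the endometrial and ovarian lines, shared 31 genes that passed limma's test against the other 5 lines, 28 of them higher. PAX8 was at 45.7, 184.5 and 72.5 in these lines and at most 5.84 elsewhere, SOX17 at 10.3, 56.1 and 26.7 against at most 0.0621, and EMX2, a homeobox gene, at 34.8, 8.72 and 14.7 against at most 0.311. Interferon-inducible genes were among them: IFITM3 was at 234.6, 286.7 and 274.4 against at most 9.21, and MX1 and HERC5 were higher by 4.16 (SE 0.63) and 3.46 (SE 0.49) on the log2 scale. FGF18, a fibroblast growth factor gene, was at 85.9, 7.07 and 114.9 against at most 0.164. The 3 lower genes were TMEM246, B4GALNT1, which encodes a ganglioside synthase, and MANEAL. This split was picked because it called the most genes, so its adjusted p-values carry that choice.

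Some genes were at low levels in particular lines, with the levels of the other lines given for SMARCA4 only. SMARCA4, a chromatin remodelling ATPase gene, was at 1.68 in H661 and 4.44 in H522 and at 28.9 to 106 in the other lines. SMARCA2, its paralog, was at 0.0282 in H522. YAP1 was at 0.0586 in H146, and RB1, a cell cycle gene, at 2.31 there. These genes were chosen after their values were seen, and no variant was examined.

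The level of 47 interferon-response genes past the filter was 1.81 in H522, 1.74 in H661 and 1.60 in H146 (1.72 ± 0.11, SD, n = 3, log2 scale), against 1.81 in H716, 2.39 in 1321N1, 2.99 in KLE, 4.08 in HEC59 and 4.14 in COV318 (3.08 ± 1.03, SD, n = 5). The exact permutation test, two-sided, gave p = 0.0536 over 56 arrangements, and 0.0536 to 0.143 over its alternatives, with p = 0.0714 over all 51 genes, where H716 (1.69) lay below H522 (1.70). Scaling of FPKM between lines is argued against by a difference of -1.35 after quantile normalization beside -1.37 as deposited. A lower response in lines of lung origin may account for it, and so may a higher one in the endometrial and ovarian lines, without which the difference was -0.386 (exact permutation p = 0.1, the smallest that 10 arrangements allow), and camera with an estimated correlation gave p = 0.0865 for lung against the other lines (median -1.10, 43 of 47 genes lower), p = 0.0896 for endometrial against the others (median 1.21) and p = 0.0330 for lung against endometrial lines (median -1.71, fry p = 0.0178, 13 genes lower when adjusted over the list alone), which both explanations predict. These explanations cannot be told apart with 3 lung lines of different kinds and with lines left out after their levels were seen.

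The score of 14 MAPK feedback targets had r = 0.642 with the ERBB4 level (exact permutation p = 0.0749, two-sided; rho = 0.310, p = 0.462), 0.576 within sets of lines (exact permutation p = 0.220) and 0.483 without SPRY1 and DUSP6, which prompted the test (exact permutation p = 0.233, 12 genes). Singly, r was above 0 for 11 of the 14. It was largest for SPRY1, an inhibitor of receptor tyrosine kinase signalling, at 0.923 (rho = 0.905), which carries no test because SPRY1 was noticed first. By rho no gene passed, SPRY1 included (adjusted p = 0.0639, exact permutation). By r no other gene passed. Among the other genes the smallest adjusted p was 0.126 for SPRED2 by r and 0.108 for PHLDA1 by rho (exact permutation). PHLDA1 ran the opposite way with r = -0.530 and rho = -0.833 (exact permutation p = 0.0154), DUSP4 had r = -0.242 and SPRY2 -0.164. Scaling between lines is argued against by an r of -0.176 between ERBB4 and housekeeping genes, but a relation that any genes of like level would show stays open: the mean r of the 12 genes lay at percentile 98.1 of 10000 random lists, whose members correlate less with each other than the targets do (percentile 99.3). ERBB4 signalling may account for part of the pattern, but r was 0.0914 without H522 and H146. When single lines were left out, r ranged from 0.166 to 0.759 (exact permutation p 0.0419 to 0.702). The lowest r was that without H146, so the relation rests mainly on that line. With 8 lines the ERBB4 level cannot be told apart from other features of H146, which had both the lowest ERBB4 level and the lowest score.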
